A study of Homo sapiens with 17 samples.

How the data were processed

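Newly made RNA was measured by SLAM-seq in SNU-761, an established human liver carcinoma cell line. In this assay cells take up thiouridine, the RNA is treated with iodoacetamide, and the alkylated thiouridine is read as C in place of T during sequencing. Reads with T>C conversions are therefore taken as RNA made while the label was present, above a background of conversions that arise without it. The table covers 17 libraries: 15 from labelled cells collected at 4 h of treatment and 2 from cells that received no thiouridine, 1 in each of the 2 experiments. Libraries were made from 3′ ends with a QuantSeq kit, per the labels' protocols.

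The deposited values are raw counts per gene, and the authors made them from the reads that they assigned to newly made transcripts with the SLAM DUNK pipeline, per the series design text. The reads were placed on build GRCh38, per the submitters' processing notes. The pipeline's version, the annotation, the number of T>C conversions needed per read and the handling of reads that fit several genes are not given in the sources used here. Each column is 1 library, and all 17 columns were matched to a sample by name. The table lists 19867 Ensembl gene IDs with no gene names. The table of gene names used here, for assembly GRCh38.p14, held 0 genes with an Ensembl ID, so 0 IDs were matched to a symbol. Genes are therefore given by ID, at most 2 in each direction for each comparison. The 23 gene lists fixed for this study, targets of the TEAD transcription factors among them, were not tested here, because the files do not pair IDs with names.

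Libraries were grouped by treatment and dose from the sample titles. The VT107 experiment had 2 libraries per group and the intetumumab experiment had 3, and each experiment was fitted on its own with all of its labelled libraries sharing 1 estimate of the spread. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Genes with too few counts were removed with edgeR's filterByExpr (minimum count 10), which left 10083 genes in the VT107 experiment and 9024 in the intetumumab experiment. Counts were scaled by TMM, which also holds for all counts per 1e6 (CPM) given, and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided. P-values were adjusted over genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Each dose was compared with its control, and the doses were compared directly. The difference between the effects of VT107 at 2.15 µM and intetumumab at 5 µg/ml was tested in 1 fit of all 15 labelled libraries (10227 genes). Fold changes of doses and agents were correlated across genes, which are not independent replicates. For the 2 doses of 1 agent, which share control libraries, the correlation was set beside 20 draws of simulated counts with no change in any group.

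Labelled libraries held between 435343 and 1778876 counts. Counts between replicates differed by more than counting noise in every pair (chi-square per degree of freedom 3.82 to 9.11), with Spearman correlations between 0.828 and 0.932, which does not tell separate cultures from repeat libraries of 1 culture. Every library was counted as a separate sample. Intervals and lower bounds given here cover counting error only, since reads of 1 molecule copied during amplification are not independent. A fold against a group with no counts is given as a lower bound, computed from 3 counts over that group.

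The fit was tested on simulated counts with the real means and library sizes, with 200 genes changed in each of 5 draws. For VT107 at 2.15 µM, 53.2% of 4-fold rises, 28.4% of 4-fold falls, 4.4% of 2-fold rises and 0.8% of 2-fold falls were recovered, and 11.8% of the calls were false. For VT107 at 0.1 µM the shares were 46.4%, 17.2%, 3.6% and 1.6%, with 9.95% of calls false. For intetumumab at 5 µg/ml they were 81.2%, 49.6%, 30.8% and 15.6%, with 6.54% false, and at 1.5 µg/ml 85.2%, 54.8%, 22% and 19.2%, with 7.17% false. Most changes of 2-fold were thus below what these libraries can detect.

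The counts of 1455 of 9758 genes examined (14.9%) shared a common divisor above 1 over all labelled libraries, where 0.707 genes were expected by chance. These genes held 13.0% of the labelled counts, and the divisor reached 21. Genes were examined when they had counts in at least 8 libraries and at least 20 counts in 1. The counts were tested as deposited, and dividing each such gene by its divisor was an added alternative. Where a named gene has such a divisor, the text says so.

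The comparisons, tests, gene naming rule and most alternatives were fixed before the data were examined. By that rule, the genes with the largest called rises and falls whose treated libraries all lay beyond all controls were named, and the genes with the smallest unadjusted p were given as values where fewer than 5 passed. The difference between agents was treated alike without the condition on libraries. The rule also named TEAD targets, other list members and 9 integrin and Hippo pathway genes by symbol, which are not analysed here. Because IDs are not paired with names, only the 2 leading IDs in each direction are printed, and in places 1. The gene with the most counts, the genes measured in the unlabelled libraries and the gene called with both agents were singled out after their values were seen.

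Alternatives fixed in advance were DESeq2 size factors or the total count in place of TMM, the Wald test of DESeq2 1.42.0, no filter beyond 1 count, at least 30 counts in each library of a group, and removal of genes whose control mean was under 3 times the unlabelled count. Fits of the compared groups alone, of all labelled libraries, with replicate number as a block and without each replicate were also fixed. Chosen after seeing the data were the divided counts, a fit without the 2 shallowest labelled libraries, pooled doses, lists of 100 genes followed from 1 agent to the other, and the cell cycle genes supplied by ID with scran 1.30.0. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. Figures were drawn with matplotlib.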

Results

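The series asks what happens to transcription in SNU-761 liver carcinoma cells within 4 h of 2 agents. VT107 is a small molecule that inhibits the TEAD family of transcription factors, the DNA-binding partners of YAP and TAZ at the end of the Hippo pathway. It was given at 0.1 and 2.15 µM and compared with DMSO, with 2 libraries per group. Intetumumab, here a biosimilar, is an antibody against integrins that contain the ITGAV chain, which bind matrix proteins at the cell surface. It was given at 1.5 and 5 µg/ml and compared with an isotype IgG1 at 5 µg/ml, with 3 libraries per group. Only reads assigned to newly made RNA were counted. Total counts were 1001568 and 1103024 in the DMSO libraries, 846103 and 789214 at 0.1 µM and 1778876 and 1247990 at 2.15 µM. They were 753142, 751380 and 950281 in the isotype libraries, 753473, 874304 and 481424 at 1.5 µg/ml, and 435343, 742611 and 783734 at 5 µg/ml. The files do not pair gene IDs with gene names, so genes appear by ID.

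**Figure D1:**
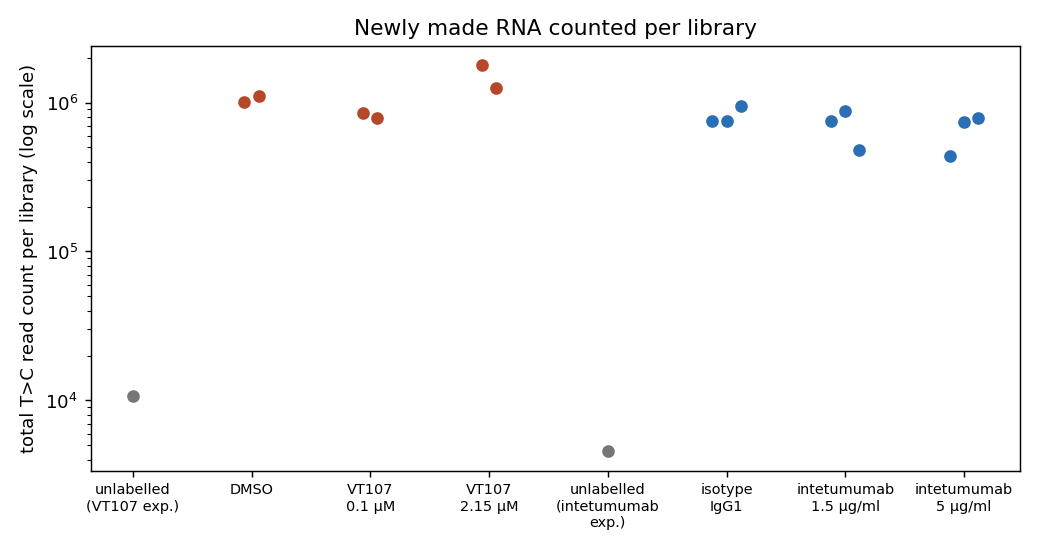
Total T>C read count of each of the 17 libraries (points, log scale on the vertical axis) by group. Labelled libraries held between 435343 and 1778876 counts, and the 2 unlabelled libraries held 10702 and 4553.

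The unlabelled libraries give the background of T>C reads that arise without thiouridine. They held 10702 counts in the VT107 experiment and 4553 in the intetumumab experiment, which was 0.949% and 0.628% of the mean labelled library. All reads sequenced per library were not compared, so a low total may also reflect fewer reads. The 3 genes counted most often were the same in both, and the first of them held 388 of the counts (3.63%) and 396 of the counts (8.70%). Among genes with at least 10 unlabelled counts, 19 of 214 and 17 of 60 exceeded a level of 1/3 of their labelled mean. With 1 unlabelled library per experiment, these are values without a replicate check.

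At 2.15 µM of VT107, edgeR called 11 genes with less new RNA than in DMSO, and no rise. The 11 genes fell between 2.25- and 4.93-fold (log2 fold changes -1.17 to -2.30, median -1.63), and all 11 lay at or above percentile 93.3 of tested genes by mean count. The largest fall was that of ENSG00000171223, from 1827 ± 421 counts per 1e6 after TMM scaling (CPM) in DMSO to 370 ± 49.4 (SD, n = 2 each), a log2 fold change of -2.30 (SE 0.22, adjusted p = 0.0193). ENSG00000095752 fell from 2102 ± 516 to 528 ± 35.6 CPM (log2 fold change -1.99, SE 0.21, adjusted p = 0.0193). Both genes stood higher in DMSO than with the isotype of the other experiment, which was scaled apart (758 ± 18.2 and 391 ± 22.3 CPM, n = 3). All falls rest on the same 2 DMSO libraries, so a high level there cannot be told apart from an effect of VT107. The gene with the most counts in the DMSO libraries went from 2.82% ± 0.204 of all T>C reads to 1.01% ± 0.0922, with a log2 fold change of -1.63 (SE 0.11) and the smallest adjusted p, 0.00310. The leading values in the other direction did not pass: ENSG00000189042 had 1 count in the DMSO libraries and 160 at 2.15 µM (adjusted p = 0.0521), and ENSG00000188186 was at 6.60 ± 0.231 and 49.7 ± 1.61 CPM (log2 fold change 2.89, SE 0.43, adjusted p = 0.0636).

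Over the 10083 genes tested at 2.15 µM, an unadjusted p under 0.05 was reached by 532 genes with higher and 635 with lower values, where 504 in all were expected without any change, and 44.7% of genes had groups that did not overlap, against 33.3% by chance. In 4 equal bins of genes from the fewest to the most counts, 123, 130, 128 and 151 genes were higher and 47, 72, 149 and 367 lower at that level. Falls over rises came to 1.19 over all genes, and to 0.511 under total count scaling, which shifts all genes alike, so this tally does not settle which direction prevailed. DESeq2 called 253 genes (57 rises and 196 falls). Scaling by the total count, which moved the median of all genes from 0.03 to 0.18 on the log2 scale, left 5 falls. Further settings gave between 1 and 199 calls, with up to 74 rises. Falls outnumbered rises in all 14 alternatives. The count also depended on single libraries and moved when any 1 library of the 2 groups was left out. All 11 genes stayed lower each time, with the weakest log2 fold change between -1.11 and -1.23. They were chosen for lying apart in these same libraries, so this was likely in advance.

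**Figure D2:**
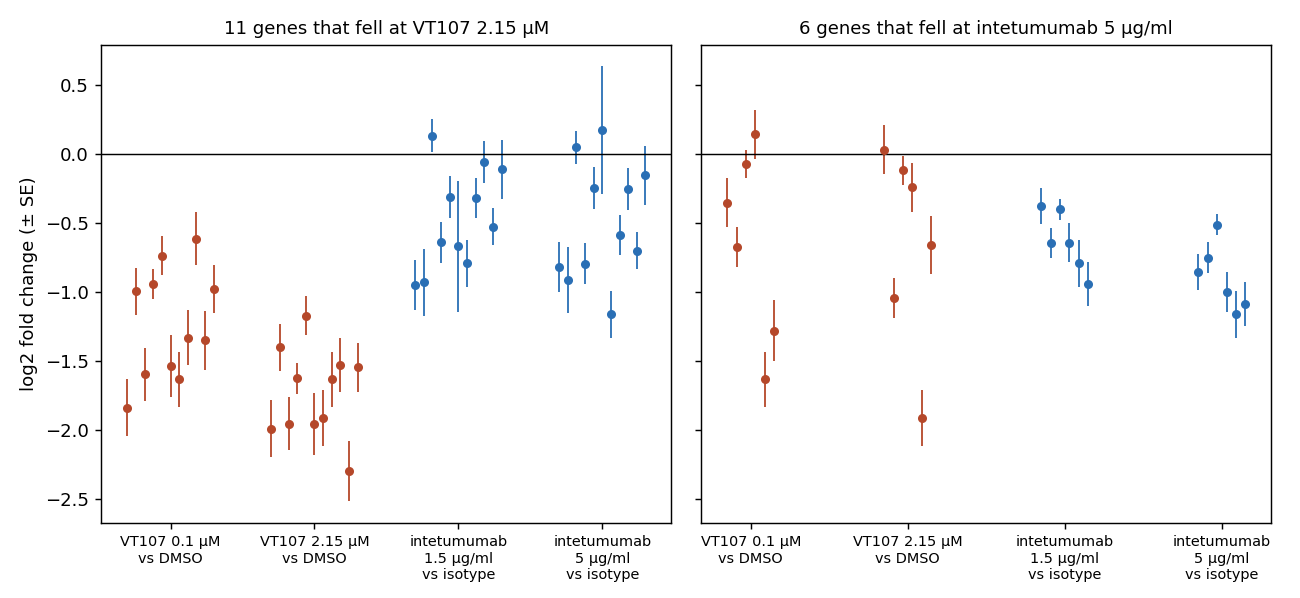
Log2 fold changes (points, with bars of 1 SE) of the 11 genes that fell at VT107 2.15 µM (left) and of the 6 genes that fell at intetumumab 5 µg/ml (right) in each of the 4 comparisons with a control; genes stand in 1 order within each comparison. All 11 genes at the left lay below 0 at both VT107 doses, and 9 of them lay below 0 at intetumumab 5 µg/ml.

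At 0.1 µM no gene passed the threshold with edgeR (smallest adjusted p 0.0617), and the values of the 11 genes were lower here too. Their median log2 fold change was -1.33, all 11 had an unadjusted p under 0.05, and 11 passed when adjusted over the list alone, although the list was chosen on libraries that share the DMSO controls and is not independent evidence. ENSG00000095752 was at 587 ± 42.9 CPM (log2 fold change -1.84, SE 0.21, adjusted p = 0.0617). In the other direction, ENSG00000118785 was at 47.4 ± 17.9 CPM in DMSO and 273 ± 27.1 at 0.1 µM (log2 fold change 2.53, SE 0.33, adjusted p = 0.0761).

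Of 10083 genes at 0.1 µM, 603 higher and 616 lower ones had an unadjusted p under 0.05, against 504 expected in all, and 39.7% had groups that did not overlap (33.3% by chance). The count of 0 depended on the method, since DESeq2 called 188 genes (57 rises and 131 falls), a fit without the filter on low counts called 171 (72 rises and 99 falls), and a fit of all labelled libraries called 72 (29 rises and 43 falls).

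The 2 VT107 doses, which share their controls, gave like profiles. Fold changes against DMSO correlated across 10083 genes with Pearson's r of 0.718 and Spearman's rho of 0.654, and 74.5% of genes had the same sign. Simulated unchanged groups, sharing simulated DMSO libraries, gave r of 0.503 (0.477 to 0.536 over 20 draws). They gave rho of 0.471 and the same sign in 66.7% of genes. The simulation gave all groups the same spread per gene. The real DMSO pair differed most (chi-square per degree of freedom 9.11, against 6.16 at 0.1 µM and 5.09 at 2.15 µM). A noisier shared control raises r without any change, so the simulated values may be too low. The covariance was 0.644, against 0.229 in the simulation, a difference of 0.415. The 2 DMSO libraries are too few to split between the doses, so how much of the excess comes from sharing them is not known. Without replicate 2 of the 0.1 µM group r was 0.448.

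Set directly against each other, the doses differed in no gene by edgeR (smallest adjusted p 0.886). An unadjusted p under 0.05 was found for 256 higher and 278 lower genes against 504 expected, and groups did not overlap in 39.1% of genes (33.3% by chance). ENSG00000137331, the gene with the most counts, had a log2 fold change of -0.69 between 2.15 and 0.1 µM (SE 0.11, adjusted p = 0.886), from 1.58% ± 0.157 to 1.01% ± 0.0922 of all T>C reads. DESeq2 called 7 genes (2 rises and 5 falls), and a fit without the filter on low counts called 4.

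At 5 µg/ml, intetumumab raised 2 genes and lowered 6. The rises were in genes at percentiles 36.5 and 63.4 by mean count. ENSG00000077063 went from 7.93 ± 3.53 CPM with the isotype to 53.6 ± 9.36 (SD, n = 3 each), a log2 fold change of 2.73 (SE 0.39, adjusted p = 0.0231). ENSG00000073737, all of whose counts were multiples of 6, went from 32.2 ± 7.03 to 117 ± 17.7 (log2 fold change 1.85, SE 0.28, adjusted p = 0.0231). Its raw counts were 18 to 36 with the isotype and 54 to 102 at 5 µg/ml. Fewer reads lie behind them if reads were counted repeatedly. The call was lost in 11 of 17 alternatives, and that of ENSG00000077063 in 10 of 16. The 6 falls were between 1.43- and 2.24-fold (log2 fold changes -0.51 to -1.16), all at or above percentile 90.8 of genes by mean count. ENSG00000142949 fell from 915 ± 54.4 to 408 ± 45.3 CPM (log2 fold change -1.16, SE 0.17, adjusted p = 0.0231), and ENSG00000167767, with even counts in every library, fell from 363 ± 21.1 to 171 ± 11.9 (log2 fold change -1.09, SE 0.16, adjusted p = 0.0231).

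Of 9024 genes tested at 5 µg/ml, 391 higher and 442 lower ones had an unadjusted p under 0.05, against 451 expected in all, and 15.9% had groups that did not overlap, against 10% by chance. No call remained without isotype replicate 1, 2 or 3 or without replicate 1 or 2 of the 5 µg/ml group (647, 684, 722, 738 and 1106 genes at an unadjusted p under 0.05), and 3 falls were called without replicate 3 of that group. DESeq2 called 92 genes (26 rises and 66 falls), and without both of the shallowest labelled libraries, left out together after the data were seen, edgeR called 0 (811 genes at an unadjusted p under 0.05).

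**Figure D3:**
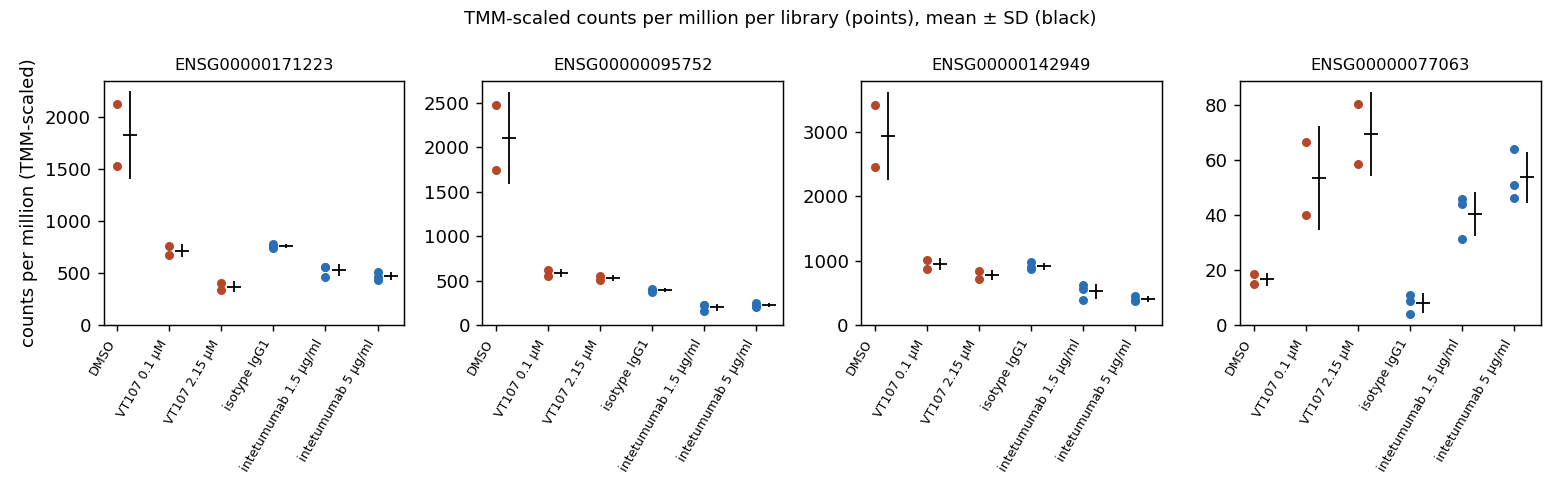
CPM of 4 genes in each labelled library (points) with the mean and SD of each group (black). New RNA of ENSG00000142949 was at 2940 ± 689 CPM in DMSO, 779 ± 79.4 at VT107 2.15 µM, 915 ± 54.4 with the isotype and 408 ± 45.3 at intetumumab 5 µg/ml.

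At 1.5 µg/ml, edgeR called no gene (smallest adjusted p 0.171). The 6 genes that fell at 5 µg/ml had a median log2 fold change of -0.64 here, each with an unadjusted p under 0.05, again against the same isotype libraries. ENSG00000077063 was at 40.4 ± 7.88 CPM (log2 fold change 2.33, SE 0.39, adjusted p = 0.171) and ENSG00000167767 was at 189 ± 11.8 (log2 fold change -0.94, SE 0.16, adjusted p = 0.171). Unadjusted p-values under 0.05 were found for 217 higher and 277 lower genes, against 451 expected in all, and groups did not overlap in 12.3% of genes (10% by chance). DESeq2 called 32 genes (4 rises and 28 falls), and a fit of these 2 groups alone called 1.

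Between 5 and 1.5 µg/ml 1 gene differed. ENSG00000196998 had no counts in the 3 libraries at 5 µg/ml, against 52.9 ± 6.61 CPM at 1.5 µg/ml (113 counts in all) and 11.9 ± 4.45 with the isotype, so that it was at least 34.5-fold lower at 5 than at 1.5 µg/ml (adjusted p = 0.0128). By edgeR, 243 higher and 266 lower genes had an unadjusted p under 0.05 (451 expected in all), and 10.8% had groups that did not overlap (10% by chance). The call was lost without replicate 1 or 2 of the 1.5 µg/ml group or replicate 3 of the 5 µg/ml group (453, 472 and 481 genes at an unadjusted p under 0.05), 2 genes were called without replicate 2 of the 5 µg/ml group, and DESeq2 called 6 genes, this one not among them. Across 9024 genes the fold changes of the 2 doses against the isotype correlated with r of 0.477 and rho of 0.499, where simulated unchanged groups gave 0.484 and 0.453. The covariance was 0.136 against 0.111 simulated, a difference of 0.0247.

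The 2 agents were set beside each other at their higher and lower doses, with no control library shared. Profiles were weakly alike: across 8847 genes, r was 0.109 and rho 0.153 between VT107 2.15 µM and intetumumab 5 µg/ml, and r was 0.0847 and rho 0.0985 between the lower doses. Single libraries mattered: r for the higher doses was 0.0662 without DMSO replicate 2, 0.0694 without VT107 2.15 µM replicate 1 and 0.0568 without intetumumab 5 µg/ml replicate 2. For the lower doses r was 0.0331 without VT107 0.1 µM replicate 2, 0.0330 without isotype replicate 2, and 0.0417, 0.0387 and 0.0189 without replicates 1, 2 and 3 of intetumumab 1.5 µg/ml, the last with rho of 0.0573. Among genes above the median in mean count the values were 0.217 and 0.207 for the higher doses and 0.163 and 0.146 for the lower doses. Of the 11 genes that fell with VT107 and the 6 that fell with intetumumab, 1 was called in both. Among the 724 genes in the top 10% by mean count in both experiments, which hold 10 and 6 of these, independent lists would share 0.0829. The falls lay higher still (median percentiles 99.3 and 99.2), so this expectation is too low for genes of their level. An overlap of 1 gene is little evidence of a shared effect. This gene, ENSG00000142949, fell from 2940 ± 689 to 779 ± 79.4 CPM with VT107 2.15 µM (log2 fold change -1.92, SE 0.20, adjusted p = 0.0193). Over all 11 VT107 genes, the median log2 fold change at intetumumab 5 µg/ml was -0.59, with 9 lower and 6 of these at an unadjusted p under 0.05.

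**Figure D4:**
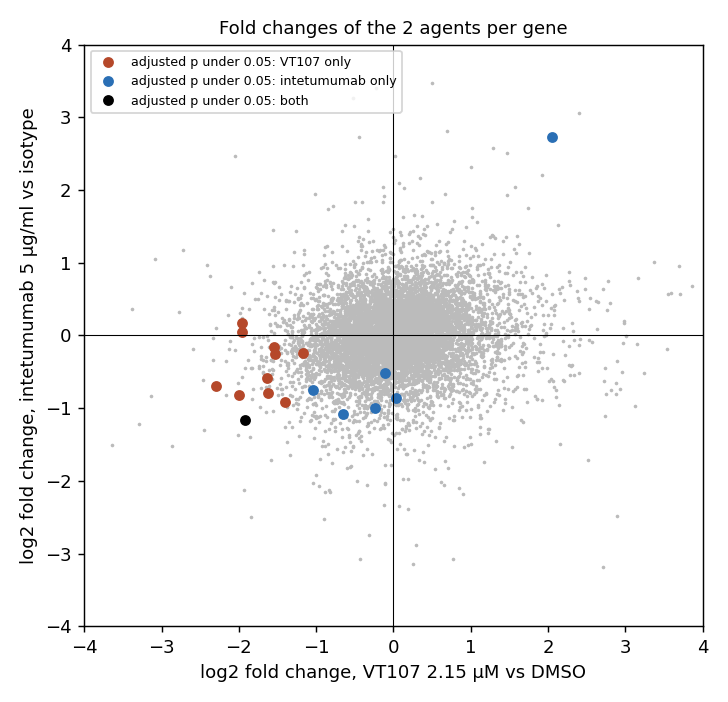
Log2 fold changes of VT107 2.15 µM against DMSO (horizontal axis) and of intetumumab 5 µg/ml against the isotype (vertical axis) for 8815 of the 8847 genes tested in both, with 32 genes beyond the axes not drawn. Coloured points passed an adjusted p of 0.05 with 1 agent, and the black point, called with both, lies at -1.92 and -1.16.

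A direct test of the difference between the effects of VT107 2.15 µM and intetumumab 5 µg/ml called 8 of 10227 genes, 4 in each direction. ENSG00000125148 fell with VT107, from 1563 ± 288 to 403 ± 26.1 CPM, and stood at 654 ± 10.6 with the isotype and 678 ± 64.0 with intetumumab (difference in log2 fold change -2.00, SE 0.20, adjusted p = 0.000508). It stood higher in DMSO than with the isotype, so its difference also rests on its level in the 2 DMSO libraries. ENSG00000187193 had log2 fold changes of -3.38 with VT107 (adjusted p = 0.0636) and 0.37 with intetumumab (adjusted p = 0.667), a difference of -3.75 (SE 0.51, adjusted p = 0.0103). The difference was positive for ENSG00000144554, at 3.71 (SE 0.63, adjusted p = 0.0360), with log2 fold changes of 3.53 and -0.19. This gene had only 3 and 4 counts in the DMSO libraries (3.54 ± 0.457 CPM), and 42.5 ± 19.5 CPM at VT107 2.15 µM. It stood at 60.3 ± 9.67 with the isotype and 52.3 ± 12.1 with intetumumab, so its difference rests on low counts in DMSO. For ENSG00000083812 the difference was 2.96 (SE 0.50, adjusted p = 0.0360), with log2 fold changes of 0.85 and -2.10.

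At an unadjusted p under 0.05, 500 genes had a positive and 427 a negative difference, against 511 expected in all, and DESeq2 called 101 genes (32 positive and 69 negative). The count was 1 without DMSO replicate 1 or VT107 2.15 µM replicate 2, 25 (12 positive and 13 negative) without DMSO replicate 2, 2 without any 1 isotype library, 4 without VT107 2.15 µM replicate 1 or intetumumab 5 µg/ml replicate 1 or 2, and 5 without intetumumab 5 µg/ml replicate 3, but ENSG00000125148 was called under all 19 alternatives run.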

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

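The levels at which unlabelled and labelled counts were compared, and the tests of scaling, of rises against falls and of what DMSO replicate 1 contributed to the falls, were chosen only after the results were seen. The comparison of unlabelled with labelled counts, the fits without each replicate and the test of the difference between agents were planned.

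In the unlabelled libraries, 5 genes of the VT107 experiment and 1 gene of the intetumumab experiment were counted more often than in the mean labelled library of the same experiment, among genes with at least 10 unlabelled counts. The 5 genes had 12 to 56 unlabelled counts, and the 1 gene had 20, against a labelled mean of 11.2. None was above its labelled mean in both experiments (0 genes), while 8 genes were above 1/3 of it in both. These are raw counts not scaled for sequencing depth, and no explanation of them was tested.

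The effects of VT107 2.15 µM and intetumumab 5 µg/ml differed in 8 genes by edgeR's direct test of the difference. In 4 of them the difference was negative, with a median of -1.86 on the log2 scale, and 3 of these lay in the top 10% by mean count. The 4 positive ones had a median of 2.91.

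All 11 genes called at VT107 2.15 µM were falls. The choice between TMM and total count scaling shifted genes by less than the size of these falls. The median of all genes differed by 0.156 on the log2 scale between the 2 scalings, against a smallest called fall of -1.17. Mostly large falls can be called here, so a shift of that size was unlikely in advance. The comparison therefore does not test what scaling adds to the pattern of falls. Under total count scaling 5 genes were called in place of 11, all of them falls. Both scalings are computed from the same counts, so neither would show a change in the new RNA of all genes. Without the DMSO replicate 1 library, 11 of the 11 genes kept at least 50% of their log2 fold change. The same was found without any other 1 library of the 2 groups. The genes were chosen for lying apart in these same libraries, so this outcome was likely in advance and does not test what that library contributed. The absence of called rises depended on the setting: alternatives gave up to 74 rises, though falls outnumbered rises in all 14. Rises in genes with fewer counts, where fewer changes are called, stay open: over all tested genes the ratio of falls to rises at an unadjusted p under 0.05 was 1.19 with TMM and 0.511 with total count scaling, and DESeq2 called 57 rises. In simulated data 106 of the 133 recovered 4-fold rises and 68 of the 71 recovered 4-fold falls lay above the median in mean count. Rises were recovered more often than falls (53.2% and 28.4%). The simulated changes were placed at random over genes, not in genes with fewer counts, so these shares do not decide whether rises were missed there.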

How the results depend on the processing

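The divided counts, the fit without both shallow libraries, the pooled doses and the followed lists were chosen after the data were seen. Counts of calls moved with many settings, and the cause was not tested. With DESeq2 the counts were 188 for VT107 0.1 µM, 253 for 2.15 µM, 7 between these doses, 32 for intetumumab 1.5 µg/ml, 92 for 5 µg/ml, 6 between these doses and 101 for the difference between agents. Without the filter on low counts they were 171, 199 and 4 for VT107, 13 for intetumumab 5 µg/ml and 42 for the difference. With at least 30 counts they were 14 and 38 for the VT107 doses, 0 between the intetumumab doses and 17 for the difference. With all labelled libraries in 1 fit they were 72 and 155 for the VT107 doses, 15 for intetumumab 5 µg/ml and 0 between its doses. Fits of the compared groups alone gave 1 for VT107 2.15 µM, 1 for intetumumab 1.5 µg/ml, 1 for 5 µg/ml and 2 for the difference. Total count scaling gave 5 for VT107 2.15 µM, and divided counts gave 5 for VT107 0.1 µM. Without both shallow libraries, 0 genes were called for intetumumab 5 µg/ml and 0 between its doses. All 11 falls at VT107 2.15 µM were called by DESeq2, without the filter, with at least 30 counts, with all labelled libraries and with the background filter.

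Leaving out each replicate in turn gave 0 for VT107 0.1 µM, 1 to 26 for VT107 2.15 µM, 0 between the VT107 doses, 0 for intetumumab 1.5 µg/ml, 0 to 3 for 5 µg/ml, 0 to 2 between its doses and 1 to 25 for the difference between agents; these fits have fewer samples, and a lone sample was assumed to vary like the other groups. For the correlations, Pearson's r ran from 0.448 to 0.871 and Spearman's rho from 0.508 to 0.796 between the VT107 doses, from 0.377 to 0.612 and from 0.392 to 0.592 between the intetumumab doses, from 0.0568 to 0.121 and from 0.104 to 0.153 between the agents' higher doses, and from 0.0189 to 0.0773 and from 0.0573 to 0.0987 between their lower doses. Among genes above the median in mean count the last 2 pairs gave 0.217 and 0.207, and 0.163 and 0.146. Of 424 values of single named genes under alternatives, 314 kept their side of the threshold, 80 lost a call, 30 gained one and 0 changed sign.

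The replicate numbers showed no clear pairing of the samples. Same-numbered samples deviated from their group means with correlations between -0.0528 and 0.189, the highest for replicate 3 of the intetumumab doses. These values do not show whether same-numbered samples were handled together. With the replicate number as a block, 5 genes were called for VT107 2.15 µM, 1 for intetumumab 5 µg/ml, 0 between the intetumumab doses and 4 for the difference between agents, and the counts of 0 for the other comparisons did not change. Not run were the planned tests of the 23 gene lists and their alternatives, because the files do not pair IDs with names.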

Other observations

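The pooled doses, the cell cycle lists, the followed lists with their tests and the tests of common divisors were chosen only after the data were seen, and the exchange of libraries between 2 groups was not.

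Pooling doses gave more calls for VT107 and not for intetumumab. With both VT107 doses against DMSO, edgeR called 61 genes, 15 rises and 46 falls, and 10 of the 11 genes that fell at 2.15 µM were among them. The count was 2 without DMSO replicate 1, 18 without DMSO replicate 2, 53 and 7 without replicates 1 and 2 of the 0.1 µM group, 14 and 6 without those of the 2.15 µM group, and 25 under total count scaling. With both intetumumab doses against the isotype, 7 genes were called, 1 rise and 6 falls, against 8 at 5 µg/ml alone. This count was 0 without any 1 isotype library, without replicate 2 of the 1.5 µg/ml group or without replicate 2 of the 5 µg/ml group (537 to 704 genes at an unadjusted p under 0.05), and 11 without replicate 1 of the 1.5 µg/ml group.

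Genes that mark the G1 phase, from lists supplied by ID with scran, were lower with VT107: of 21 tested, 15 had lower values at each dose, with medians of -0.36 at 0.1 µM and -0.49 at 2.15 µM (camera, adjusted p = 0.0280 each over 12 tests). With an estimated correlation the adjusted p was 0.418 for both. None of the 21 was called by itself with edgeR (6 and 5 at an unadjusted p under 0.05). Lists for S and G2M did not pass with either agent, nor did G1 with intetumumab.

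The genes that fell most with VT107 were also lower with intetumumab. The 100 genes with the smallest p among falls at VT107 2.15 µM had a median log2 fold change of -0.35 at intetumumab 5 µg/ml, with 85 of 100 lower (camera, adjusted p = 2.41e-21, and 0.00702 with an estimated correlation). A trend with expression level is argued against, as 0 of 10000 lists matched on mean count had so low a median (percentile 0, with 95% of lists between -0.10 and 0.05). Genes whose counts share a divisor are argued against as the source, as a list chosen without them had a median of -0.31 (percentile 0, with 95% of lists between -0.09 and 0.06), while repeated counting of some reads in the remaining genes, 54.0% of whose counts of at least 20 were even, was not removed and stays open. The reverse list gave -0.44 at VT107 2.15 µM with 77 of 100 lower, a lower-dose pair gave -0.25 and -0.41, and all 4 lists of falls kept direction and call in the 21 alternatives run for each; whether this may reflect a target shared by both agents or a response to any treatment was not tested, since each agent has its own control and no other agent was used.

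Lists of rises were also higher with the other agent, above at least 98.0% of lists matched on mean count in all 4 cases. The 100 leading rises at VT107 2.15 µM had a median of 0.09 at intetumumab 5 µg/ml (60 of 100 higher, camera adjusted p = 0.0110, and 0.0144 with an estimated correlation), and those at intetumumab 5 µg/ml had a median of 0.20 at VT107 2.15 µM (65 of 100 higher, adjusted p = 0.000262, and 0.0672 with an estimated correlation). At the lower doses the medians were 0.17 and 0.20, with 62 of 100 higher in each (adjusted p = 0.00306 and 0.0428, and 0.00908 and 0.0672 with an estimated correlation). The 4 lists of rises lost the call in 5, 2, 1 and 7 of 21 alternatives.

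Counts with a common divisor, in 1455 genes where 0.707 were expected, exceed chance (792 with a divisor of 2, 330 of 3 and 176 of 4). If each read had entered the count several times, the variance between replicates relative to the mean should be inflated, and the ratio of genes with divisor 2 to others of the same mean was 1.06 before division and 0.649 after. By the rule written before this test, a ratio under 1.2 counted against this explanation, and 1.06 met that rule. The rule was not applied, a decision taken after the ratio was seen: the spread between replicates exceeds counting noise, and the genes without a divisor hold the same feature, with 54.0% even values among 87299 counts of at least 20 (95% confidence interval, exact, 53.6% to 54.3%). Repeated counting of reads thus stays open, and no biological explanation was tested.

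Whether libraries exchanged between groups give as many calls was counted for the intetumumab experiment. For 5 µg/ml against the isotype, 1 of the 10 splits of the 6 libraries, the real one, gave 8 calls, and the highest of the others gave 0. For 1.5 µg/ml all 10 of 10 splits gave 0, and between the doses 2 of 10 gave 1 or more, the highest other being 1. A total of 10 splits is too few for a share under 0.05. For the pooled doses, 1 of 84 splits, the real one, gave as many as 7 calls and the highest other gave 1. A count that high thus came only from the real split. Pooling was chosen after the data were seen, so this does not exclude a chance assignment of libraries. The real split did not have the most genes at an unadjusted p under 0.05: it had 705, and 3 other splits had more, up to 1229 with 0 calls in the split that parts replicate 3 of 1.5 µg/ml and replicates 1 and 3 of 5 µg/ml from the rest. The 7 calls also fell to 0 without any 1 isotype library or without replicate 2 of either dose.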
